A study of Drosophila melanogaster with 4 samples.

How the data were processed

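RNA was recovered by anti-GFP immunoprecipitation (IP) from extracts of Drosophila melanogaster larvae and hybridised to 2-colour arrays. The GMR driver, which is active in the developing eye, expressed either GFP fused to dASF/SF2, an SR-family splicing factor, or GFP with a nuclear localisation signal (GFP-NLS), the control. Per the labels' protocols, each extract held the anterior ends of 600 third-instar larvae. There were 4 arrays, each comparing a dASF/SF2 IP with a GFP-NLS IP. On 2 arrays the dASF/SF2 IP was labelled with Cy5 and the GFP-NLS IP with Cy3, and on 2 arrays the dyes were exchanged. Per the labels, arrays of 1 replicate number are dye swaps of each other, so the 4 arrays were treated as 2 replicates. Nothing beyond the replicate numbers states that the replicates came from separate cultures of larvae, so p-values measure the spread between these samples, which may be technical.

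The values used were the authors' deposited log ratio of each probe on each array. The authors' background correction, normalisation, filtering, scale and software are not given in the sources used here. The base of the logarithm is unstated, so values are given in log-ratio units and no fold is printed except as a count under a named base. The numerator of the ratio is also unstated. The column medians were 0.010 and 0.013 for the arrays with dASF/SF2 in Cy5 (replicates 1 and 2), and 0.006 and 0 for those with dASF/SF2 in Cy3, so each array had been centred near 0. A value of -10000 stood in 73 cells as a marker for a ratio without a logarithm and was read as missing. No scanner signals were used, so intensity, background and saturation of the spots were not analysed here, and the number of arrays limits the precision. The columns held 14876 and 15330 measured probes for the arrays with dASF/SF2 in Cy5, and 13815 and 14616 for those with dASF/SF2 in Cy3, of 15744 probes listed.

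Probes were named through GEO's platform annotation, in which 13147 probes had 1 gene symbol, 99 had several and 2498 had none. Of those with 1 symbol, 12519 matched a RefSeq gene by Entrez identifier and 628 did not, and no symbol changed by the update. Probes with several symbols were left unnamed. No genome build was named for the array, so no coordinates are printed.

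Each array was centred on its median, and the 12847 probes with a value on all 4 arrays were tested. Of these, 10850 had 1 symbol, 82 several and 1915 none, and together they covered 10353 genes, 396 of them with more than 1 probe. The rule for direction, fixed before the data were examined, was to read the values as dye ratios if both dye-swapped pairs correlated below 0 across probes, as sample ratios if both correlated above 0, and to give no direction otherwise. The pairs differed in sign, so no direction is given. The arrays with dASF/SF2 in Cy3 had their signs turned. Since the arrays were centred, a value is relative to the median probe, and a difference common to most probes cannot be seen. On that scale, if the deposited values are Cy5 over Cy3, a positive turned value means more RNA in the dASF/SF2 IP. If they are Cy3 over Cy5, it means more in the GFP-NLS IP. If they are already ratios of 1 sample to the other, the turned value is a dye effect and the unturned mean is the IP comparison. Both sets of values were therefore tested.

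The arrays of a replicate were averaged and the mean of the 2 replicates was tested against 0 with limma's moderated test (limma 3.58.1 in R 4.3.3, lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. These p-values do not depend on the base of the logarithm. A fit with a dye term, and the counts of probes with 1 sign or a ratio of 2-fold or more on all 4 arrays, were computed beside it. For genes, the probes of a symbol were averaged and the same test was run on 1 value per gene. The 21 gene lists were fixed before the data were examined, and the 20 with at least 3 measured members were tested with limma's camera at its preset correlation of 0.01. The list of transposable elements had 0 measured members. Counts within lists rest on the test with 1 value per gene, adjusted over all genes and adjusted over the list alone. The adjustment over a list alone gives each list its own cut and makes no correction for the 20 lists tried. Of all 10353 genes, 2499 had an unadjusted p under 0.05 in limma's moderated test. Members past the cut of their list therefore do not by themselves set that list apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

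The named genes were chosen by a rule fixed before the data were examined. It took, on each side, up to 10 single-symbol probes with 1 sign on all 4 turned arrays, first those past the threshold and then those of the largest mean, given as values where they did not pass. It added SF2, B52 and up to 4 members of each list, taken by the largest absolute mean after any past the threshold.

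The test was tried on simulated data with the same 12847 probes, 2 replicates and the fitted prior spread, with 50 probes changed at each size. It recovered 4 of 50 at 0.3 log-ratio units, 43 of 50 at 0.6, 49 of 50 at 1 and 50 of 50 at 2, with 7 false calls. The sizes 1 and 2 exceed every turned mean in the data (-0.87 to 0.92), and such probes loosen the Benjamini-Hochberg cut for smaller ones. In the data 0 probes passed, that of pen-2 at 0.92 included, so the recovered shares do not carry over to these arrays. Of 20 simulated lists, camera called the shifted one and 0 of the 19 others. The simulated errors were drawn independently for each probe, so this does not tell how often camera calls lists of correlated genes.

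The alternatives tried were a replicate block by duplicateCorrelation (statmod 1.5.0), the 4 arrays as independent samples, a dye term, no centring, scaling to 1 spread, a looser rule on missing values, treat, a robust prior, a looser threshold and leaving out each array. For lists they were an estimated correlation, fry and the 4 arrays as independent samples. Chosen after seeing the data were arrays not turned, single-symbol probes alone, exact zeros of 1 array read as missing, medians of 48 blocks of consecutive probe numbers, standing for position, taken off, other log bases, 1 value per gene for the count of calls, and an estimated correlation on the 4 arrays.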

Results

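The data were 4 arrays on which RNA bound by GFP-tagged dASF/SF2 in the anterior end of larvae was set against RNA recovered with GFP-NLS, to find potential mRNA targets of this SR protein in the developing eye. The 4 arrays formed 2 replicates, each a dye-swapped pair. The deposited log ratios had standard deviations of 0.269 and 0.247 on the arrays with dASF/SF2 in Cy5 (replicates 1 and 2), and 0.251 and 0.342 on those with dASF/SF2 in Cy3. Exact zeros filled 811 cells of the array with dASF/SF2 in Cy3 of replicate 2, and 0, 1 and 35 cells of the others.

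The agreement of the arrays showed what the values could tell about direction. Across the 12847 probes measured on all 4 arrays, which are not independent replicates, arrays of the same dye orientation correlated with a Pearson r of 0.435 and a Spearman rho of 0.502 (dASF/SF2 in Cy5), and 0.264 and 0.309 (dASF/SF2 in Cy3). The dye-swapped arrays of replicate 1 had an r of 0.236 and a rho of 0.191, and those of replicate 2 an r of -0.054 and a rho of -0.467. Among probes with 1 gene symbol the dye-swapped pairs had an r of 0.169 and a rho of 0.152 (replicate 1), and -0.565 and -0.576 (replicate 2). Arrays of opposite orientation from different replicates correlated below 0: r was -0.219 and rho -0.311 for dASF/SF2 in Cy5 of replicate 1 with dASF/SF2 in Cy3 of replicate 2, and -0.069 and -0.121 for the other such pair. Since the dye-swapped pairs differed in sign, values below are given on a positive and a negative side after the arrays with dASF/SF2 in Cy3 were turned, and neither side is assigned to a sample.

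The largest turned values belonged to genes of unlike function. On the positive side were pen-2, a subunit of gamma-secretase, at 0.92 ± 0.08 (SD, n = 2), MCPH1, the fly microcephalin, at 0.89 ± 0.61, and Mis12, a kinetochore protein, at 0.78 ± 0.34. The heat shock gene Hsp70Ba followed at 0.68 ± 0.21. On the negative side were Gmap, a Golgi protein, at -0.87 ± 0.16, the polyubiquitin gene Ubi-p63E at -0.87 ± 0.27, the glutathione transferase gene GstD5 at -0.86 ± 0.14, and the aldehyde oxidase gene AOX1 at -0.83 ± 0.34. SF2, the gene of the transgene, had a turned value of -0.23 ± 0.09 (SD, n = 2), negative on all 4 turned arrays, with an adjusted p of 0.158 in limma's moderated test. B52, which encodes another SR protein, had -0.056 ± 0.075 over 5 probes that differed in sign among themselves.

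The remaining genes named on the positive side were CG30471 (0.62 ± 0.10), mTerf3, of the mitochondrial transcription termination factor family (0.54 ± 0.32), CG5910 (0.53 ± 0.32), CG42807 (0.53 ± 0.17), CG3348 (0.53 ± 0.17) and the salivary gland gene ng2 (0.52 ± 0.38). Those on the negative side were jv, known from bristle shape (-0.80 ± 0.58), CG13917 (-0.79 ± 0.15), the matrix metalloproteinase gene Mmp2 (-0.74 ± 0.23), CG7916 (-0.73 ± 0.12), CG6686 (-0.69 ± 0.19) and EndoA, an endophilin of synaptic vesicle endocytosis (-0.68 ± 0.41). By the rule of choice, each of these 20 genes had 1 sign on all 4 turned arrays. Their probes had adjusted p-values from 0.117 to 0.124 in limma's moderated test, so the genes are given as values and not as calls. For 3 of them the mean moved by over 1.5 times when 1 array was left out. MCPH1 was at 0.56 and EndoA at -0.31 without the array with dASF/SF2 in Cy3 of replicate 2, and EndoA at -1.05 without that with dASF/SF2 in Cy5 of replicate 2. CG30471 differed by dye orientation, with 0.11 and 0.12 on the arrays with dASF/SF2 in Cy5 and 1.271 and 0.985 on those with dASF/SF2 in Cy3, and was at 0.33 and 0.41 without the latter arrays of replicates 1 and 2. With 1 value per gene in place of probes, 918 of 10353 genes had an adjusted p under 0.1 in limma's moderated test and 3 passed the threshold of 0.05: pen-2 with an adjusted p of 0.0396 in limma's moderated test, and Gmap and GstD5 with 0.0412 each. These calls ended when the arrays were scaled to 1 spread (adjusted p = 0.134 for each in limma), when probes needed only 1 array per replicate (0.194) and without the array with dASF/SF2 in Cy5 of replicate 2 (0.228).

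**Figure D1:**
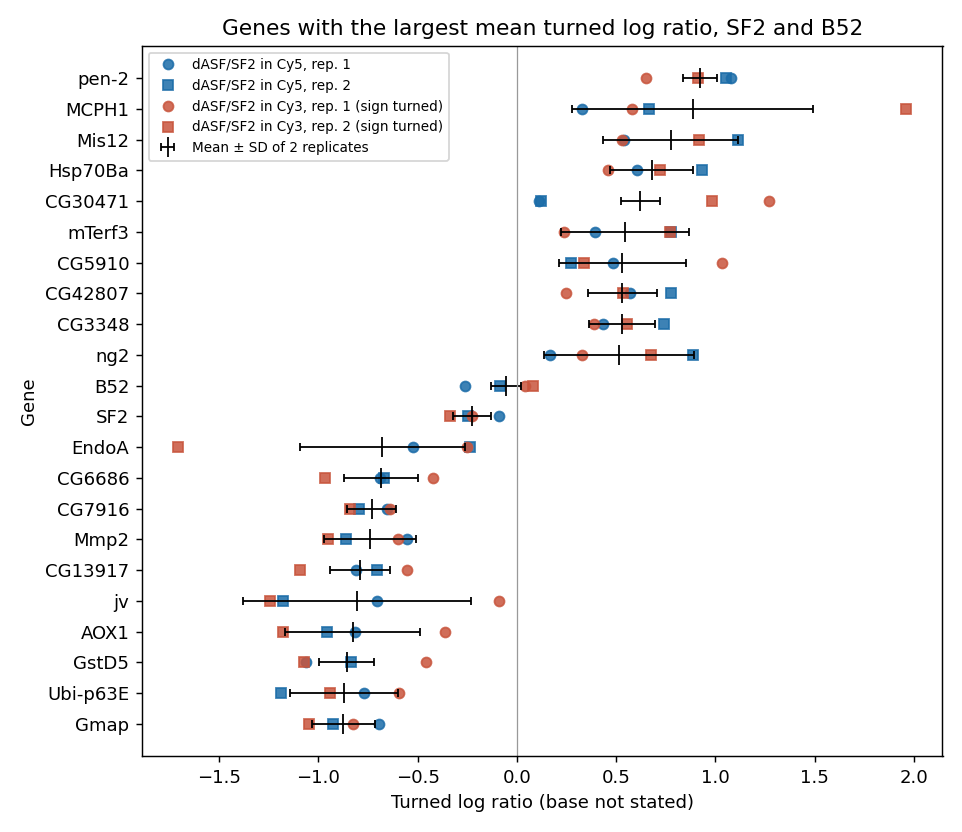
Turned log ratio (x axis, log-ratio units of unstated base) of the 20 genes with the largest mean of 1 sign on all 4 arrays, and of SF2 and B52 (y axis). Circles and squares are single arrays of replicates 1 and 2, blue with dASF/SF2 in Cy5 and red with dASF/SF2 in Cy3 and the sign turned, and the black bar is the mean ± SD of 2 replicates; pen-2 lies highest at 0.92 and Gmap lowest at -0.87.

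Over all probes, 0 of 12847 passed an adjusted p of 0.05 in limma's moderated test, and 2980 had an unadjusted p under 0.05, 1229 positive and 1751 negative, where chance alone gives 642. The smallest adjusted p was 0.117. A sign shared by all 4 turned arrays was found for 3616 probes (28.1%), 1554 positive and 2062 negative, against 12.5% by chance. The turned means of the 2 replicates correlated with a Pearson r of 0.548 across probes. With the arrays not turned, 0 probes passed, 716 had an unadjusted p under 0.05, 1746 (13.6%) shared a sign on all 4 arrays, and the replicates correlated at 0.160. Among probes with 1 gene symbol the Pearson r of the replicates was 0.234 not turned and 0.552 turned. The probe means had an SD of 0.153 not turned and 0.164 turned. In the fit with a dye term, 0 probes passed for the difference between dye orientations (2541 at an unadjusted p under 0.05) and 0 for the mean over orientations (1123).

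With the replicate number as a block, limma called 1119 probes, where the estimated correlation within a block was -0.408. That fit takes the 4 arrays as the observations. A negative correlation within a block makes its standard errors smaller than for independent arrays, so the 1119 calls rest on that estimate. On the 4 arrays without a block limma called 0, with or without a dye term. Without the array with dASF/SF2 in Cy5 of replicate 1, 184 probes passed, and without that with dASF/SF2 in Cy3 of replicate 1, 66 passed; 0 passed without either array of replicate 2. Each such fit leaves 1 replicate as a single array, so a part shared by both dye orientations no longer cancels. Probes then needed values on the remaining arrays only, so these counts are not like for like with the 0 of 12847. The replicate correlation was 0.238 and 0.383 without the arrays with dASF/SF2 in Cy5 of replicates 1 and 2. It was 0.396 and 0.408 without those with dASF/SF2 in Cy3 of replicates 1 and 2.

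**Figure D2:**
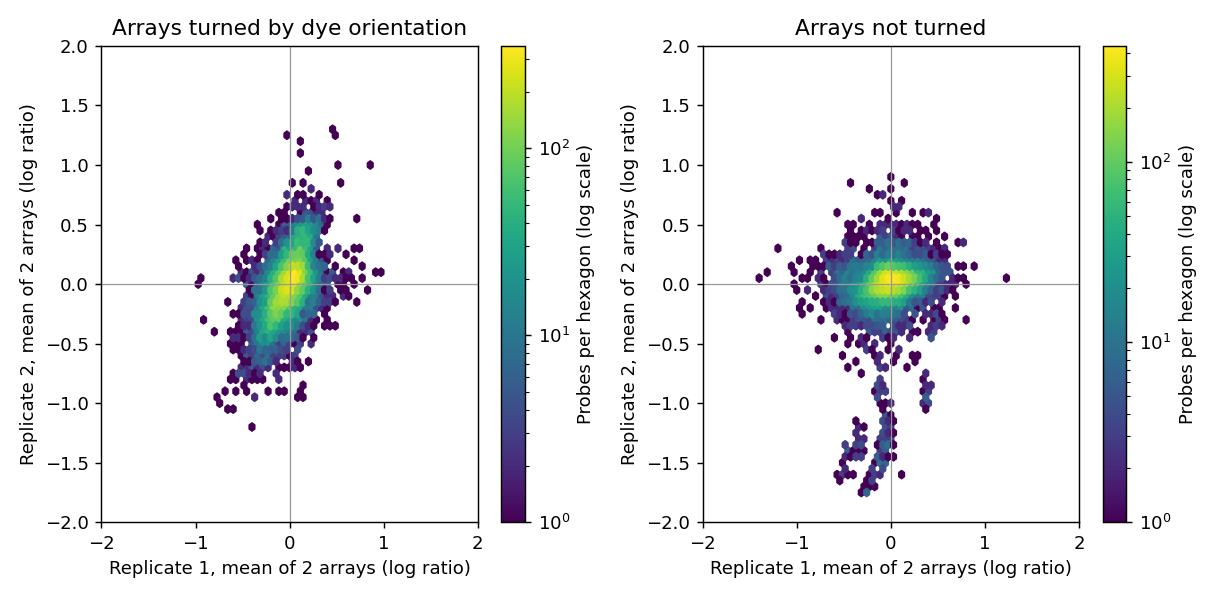
Mean log ratio of replicate 1 (x axis) against replicate 2 (y axis), each the mean of 2 arrays in log-ratio units, for 12847 probes; colour gives the probes per hexagon on a log scale. The left panel, with the arrays of dASF/SF2 in Cy3 turned, has a Pearson r of 0.548, and the right panel, with arrays not turned, 0.160 and a tail of probes that lie low in replicate 2 alone.

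Sizes were counted under each base the values could have. Read as log2, 0 probes reached 2-fold in 1 direction on all 4 turned arrays. Read as log10, 12 did so on the positive and 62 on the negative side, and read as natural logs, 0 and 1. With the arrays not turned, the counts were 0 under log2, 1 and 24 under log10, and 0 under natural logs.

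Translation factors lay together on the negative side. Of 42 measured members, 37 had negative turned values, and the list mean was -0.17 ± 0.03 (SD over 2 replicates). The largest were eIF3a at -0.42 ± 0.18, eIF5B at -0.40 ± 0.28 and eIF5 at -0.38 ± 0.20, initiation factors, and eRF1, a release factor, at -0.37 ± 0.04. An unadjusted p under 0.05 in limma's moderated test was found for 19 of the 42 members, against 2499 of all 10353 genes. Adjusted over all genes 0 members passed, and adjusted over the list alone 14 did, all with negative means. Of these, eIF5B, eIF2Balpha and eEFSec (the last 2 named after their values were seen) were positive on 1 turned array. Without the array with dASF/SF2 in Cy5 of replicate 1, eIF2Balpha moved from -0.25 to -0.079 and eEFSec from -0.24 to -0.13, and without that with dASF/SF2 in Cy3 of replicate 1 eIF2Balpha moved to -0.41. Camera gave an adjusted p of 1.29e-06 for the list at its preset correlation of 0.01, where the correlation estimated on the 4 arrays was 0.091. With a correlation estimated on the 2 replicates the adjusted p in camera was 0.996, a value near that of every list.

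Proteasome genes lay on the same side, with 28 of 36 negative and a mean of -0.13 ± 0.01. Rpn2 (-0.39 ± 0.06), Rpn1 (-0.32 ± 0.06) and Rpn5 (-0.28 ± 0.10), of the regulatory particle, and Prosalpha3 (-0.31 ± 0.01), of the core, had the largest values. Adjusted over all genes 0 members passed, and adjusted over the list alone 8 did, all negative. Camera gave an adjusted p of 2.45e-04 for the list at the preset correlation of 0.01, where the correlation estimated on the 4 arrays was 0.167. With a correlation estimated on the 2 replicates the adjusted p in camera was 0.996.

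Glial markers lay on the positive side, with 9 of 12 positive and a mean of 0.17 ± 0.09. These included Gs2, a glutamine synthetase, at 0.39 ± 0.25, Gli, gliotactin, at 0.36 ± 0.16, repo, the homeobox gene of glia, at 0.32 ± 0.06, and the astrocyte marker alrm at 0.28 ± 0.03. Adjusted over all genes 0 members passed, and adjusted over the list alone 9 did, 8 positive and 1 negative, loco at -0.22 ± 0.09, named after its value was seen. Gli was negative on 1 turned array, and its mean was 0.24 without the array with dASF/SF2 in Cy5 of replicate 1. Camera gave an adjusted p of 0.00217 at the preset correlation of 0.01, where the correlation estimated on the 4 arrays was 0.27. With a correlation estimated on the 2 replicates the adjusted p in camera was 0.996. These 3 lists were the ones called among the 20 tested, and camera called all 3 when any 1 array was left out.

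With an estimated correlation on the 4 arrays as independent samples, camera's adjusted p was 0.767 for each of the 3 lists, so none of the 3 calls held there. These calls thus rest on the preset correlation of 0.01, which lies below those estimated on the 4 arrays. On the 2 replicates the estimated correlation gave every tested list an adjusted p of 0.996 or 0.997 in camera, whatever its shift. With so few replicates that setting could hardly call any list, so its result decides nothing about these 3. Fry, which tests whether the members of a list move one way without comparing them with other genes, called 1 list, axon guidance and cell adhesion (adjusted p = 0.0381), and gave 0.251, 0.175 and 0.454 for translation factors, proteasome and glial markers. With the arrays not turned, camera instead called histones (list mean -0.13) and larval salivary gland markers (-0.076), both with an adjusted p of 0.0314, while translation factors, proteasome and glial markers had 0.865, 0.306 and 0.865.

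Genes of eye development, the tissue in which the driver is active, went both ways. Of 39 measured members of eye specification and photoreceptor differentiation, 22 were positive and 17 negative, with a list mean of -0.0041 ± 0.0031 and a median of 0.044; camera's adjusted p was 0.876. The largest values were negative: sev, the receptor tyrosine kinase of photoreceptor fate, at -0.46 ± 0.15, fj, of planar polarity, at -0.45 ± 0.06, the cadherin gene stan at -0.43 ± 0.19 and salr, a zinc finger gene, at -0.42 ± 0.24. In limma's moderated test 15 of the 39 members had an unadjusted p under 0.05, against 2499 of all 10353 genes. Adjusted over all genes 0 passed, and adjusted over the list alone 9 did. These were the 4 above and, named after their values were seen, Sos (-0.31) on the negative side and the transcription factor genes oc (0.30), sv (0.27), lz (0.27) and Optix (0.26) on the positive side. The value of sv, negative on 1 turned array, was 0.13 without the array with dASF/SF2 in Cy5 of replicate 1 and 0.41 without that with dASF/SF2 in Cy3 of replicate 1. Phototransduction genes had a mean of 0.067 ± 0.106 over 15 members, 11 of them positive, with Arr1 at 0.25 ± 0.14 and trpl at 0.21 ± 0.12 (camera's adjusted p = 0.161), and 0 passed adjusted over the list alone. Arr1 was negative, at -0.063, on the array with dASF/SF2 in Cy5 of replicate 1.

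SR proteins and splicing regulators had a mean of -0.063 ± 0.039 over 29 members, 17 of them negative (camera's adjusted p = 0.284). Adjusted over the list alone 2 members passed, with negative means: SRPK, a kinase of SR proteins, at -0.46 ± 0.10 and Psi, an inhibitor of P-element splicing, at -0.32 ± 0.02. Psi was positive on 1 turned array, and its mean was -0.15 without the array with dASF/SF2 in Cy5 of replicate 1 and -0.49 without that with dASF/SF2 in Cy3 of replicate 1. Axon guidance and cell adhesion had a mean of -0.056 ± 0.002 over 34 members (22 negative, adjusted p = 0.284), with 4 negative members past the threshold adjusted over the list alone. Its largest values were those of sdk (-0.36 ± 0.10) and of the receptor phosphatase genes Ptp52F (-0.32 ± 0.07), Lar (-0.29 ± 0.03) and Ptp10D (-0.28 ± 0.01), of which Lar was at -0.17 without the array with dASF/SF2 in Cy5 of replicate 1. Muscle markers (21 members) had a mean of -0.067 ± 0.007, and camera's adjusted p was 0.284. Adjusted over the list alone 3 members passed, with negative means: sls and bt, which encode giant muscle proteins, at -0.35 ± 0.19 and -0.34 ± 0.14, and Actn, alpha-actinin, at -0.30 ± 0.05. The value of bt, positive on 1 turned array, was -0.135 and -0.596 without the arrays with dASF/SF2 in Cy5 of replicates 1 and 2, and -0.554 and -0.092 without those with dASF/SF2 in Cy3, and sls was at -0.23 without the last of these.

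Heat shock genes and chaperones (27 members) had a mean of -0.040 ± 0.017 and an adjusted p of 0.284 in camera. The largest values were those of Hsp70Ba, DnaJ-1 (0.32 ± 0.21) and CCT5 (-0.30 ± 0.06). The probes of Hsp70Aa (0.049 ± 0.023) and Hsp70Bc (-0.12 ± 0.07), close copies of Hsp70Ba named after their values were seen, differed from that of Hsp70Ba, so its value is uncertain. Adjusted over the list alone these first 3 passed, and so did Droj2 at -0.27 ± 0.04 and Hsc70-4 at -0.26, the last named after its value was seen. Histones (7 members) had a mean of 0.090 ± 0.085 and a median of -0.0063, with the replacement histone gene His3.3B at 0.45 ± 0.37 (adjusted p = 0.570 in camera). On single turned arrays the list mean was -0.13 and 0.042 with dASF/SF2 in Cy5 (replicates 1 and 2), and 0.18 and 0.26 in Cy3. Cytosolic ribosomal proteins (33 members) had -0.020 ± 0.002, the mitochondrial respiratory chain (70 members) 0.0033 ± 0.0627, cell cycle genes (20 members) -0.026 ± 0.038, with Mcm2, a replication licensing gene, at -0.35 ± 0.01, and apoptosis genes (12 members) -0.049 ± 0.002, with the apoptosome gene Dark at -0.40 ± 0.09. Ecdysone response genes (14 members) had 0.0041 ± 0.0208 and cuticle markers (89 members) -0.015 ± 0.005. Camera's adjusted p was 0.876 for each of these 6 lists; adjusted over the list alone, Mcm2, Dark and the cuticle gene Lcp9 (-0.49 ± 0.07) passed, and 0 members of the other 3 lists.

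Markers of other tissues in the anterior end of the larva were measured in the same way. Haemocyte markers (16 members) had a mean of 0.012 ± 0.064 and a median of -0.052, with He at 0.35 ± 0.17 and the GATA factor gene srp at 0.29 ± 0.12, and 2 positive members passed adjusted over the list alone. Fat body and haemolymph markers (17 members) had a mean of 0.00080 ± 0.0631 and a median of -0.014, with 1 negative member, Fbp2 (-0.35 ± 0.003), past the threshold adjusted over the list alone. Neuronal and synaptic markers (22 members) had a mean of -0.015 ± 0.005 and a median of 0.0094, and 0 passed adjusted over the list alone. Salivary gland markers (15 members) had a mean of 0.018 ± 0.084 and a median of -0.018, with ng2 and ng1 (0.51 ± 0.39) positive and the glue genes Sgs8 (-0.30 ± 0.03) and Sgs4 (-0.27 ± 0.05) negative, all 4 past the threshold adjusted over the list alone; camera's direction for this list was negative, opposite to its mean. Sgs8 was positive on 1 turned array, and its mean was -0.12 and -0.48 without the arrays of replicate 2 with dASF/SF2 in Cy5 and in Cy3. The adjusted p of these 4 lists in camera lay between 0.988 and 0.993, and adjusted over all genes 0 members of any list passed.

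**Figure D3:**
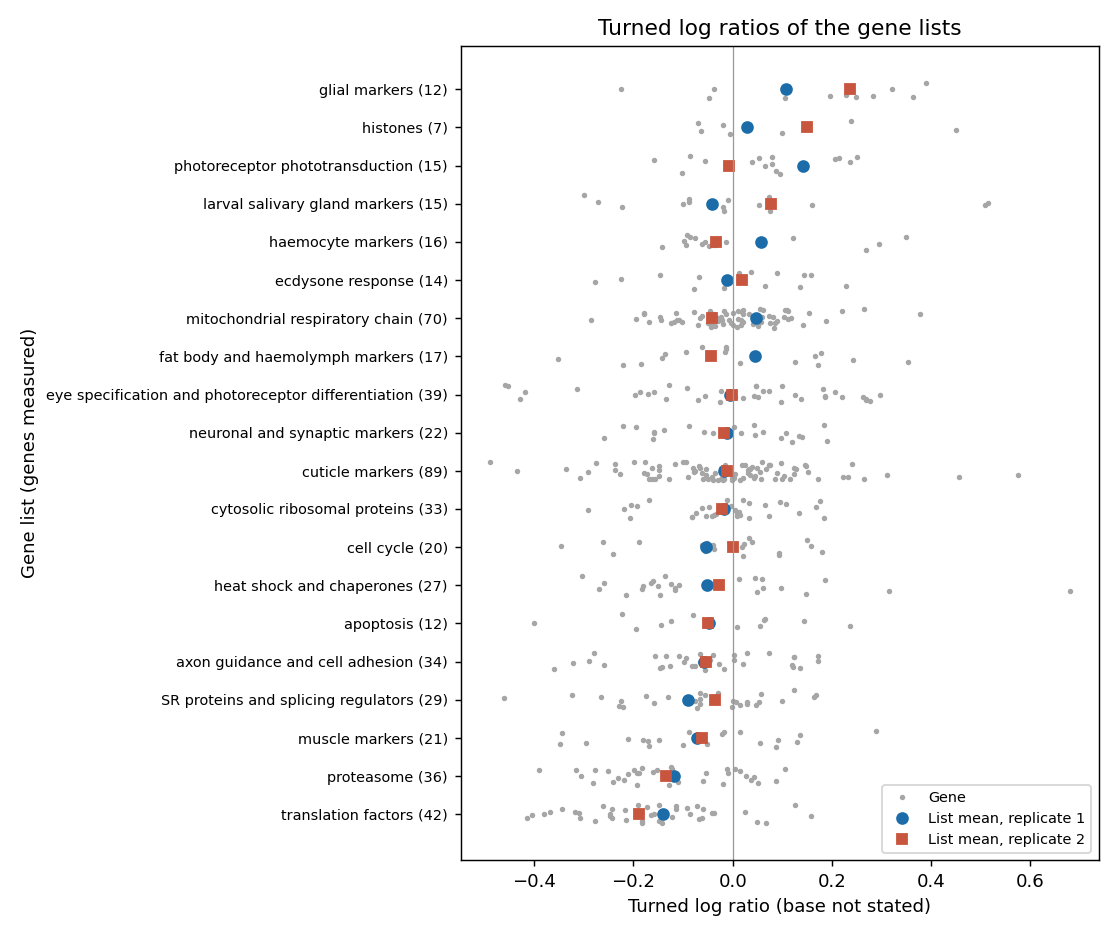
Turned log ratios (x axis, log-ratio units of unstated base) of the 20 gene lists, with the number of genes measured in brackets (y axis). Grey points are genes (means of 2 replicates), blue circles and red squares the list means of replicates 1 and 2; translation factors lie lowest at -0.14 and -0.19, and glial markers, at 0.11 and 0.24, have the highest mean over both replicates, with phototransduction above them in replicate 1 at 0.14.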

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

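Settings chosen only after the data were seen were arrays not turned, zeros read as missing, 1 symbol per probe, position blocks, other log bases, 1 value per gene (and its count at 0.1), list members with 1 array left out, and an estimated correlation on 4 arrays. The count of 0 probes past the threshold (smallest adjusted p 0.117) was 1119 with the replicate number as a block, 3 with exact zeros of 1 array read as missing and 3 with 1 value per gene, and 0 to 184 when each array was left out. It was 0 in limma without a replicate block, with a dye term, without centring (smallest adjusted p 0.0533), with scaling, treat, a robust prior, a threshold of 0.1 (by probe, but 918 of 10353 genes with 1 value per gene), at least 1 array per replicate, single-symbol probes (0.0561), position blocks and arrays not turned. The count of 0 probes at 2-fold became 4 at 1.5-fold, 74 read as log10, 1 read as natural logs, and 0 to 1 when arrays or replicates were left out. With an estimated correlation on 2 replicates, where camera gave every list an adjusted p of 0.996 or 0.997, the 3 called lists became 0. They became 0 with an estimated correlation on 4 arrays, 1 with fry, and 3 to 5 when each array was left out. Without the array with dASF/SF2 in Cy5 of replicate 1, histones (adjusted p = 0.0106) and phototransduction (0.0213) joined them, and without that with dASF/SF2 in Cy3 of replicate 2 phototransduction did (0.0362). The replicate correlation of 0.548 was 0.401 with at least 1 array per replicate, 0.160 not turned and 0.238 to 0.408 when each array was left out. The cause of these changes was not tested.

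Shifts of a list against all genes that changed sign with the arrays not turned were 0.021 for axon guidance, 0.0077 for SR proteins, -0.0065 for the respiratory chain, 0.036 for proteasome, 0.0071 for heat shock, -0.14 for histones, -0.087 for salivary gland, -0.052 for fat body, -0.0089 for haemocytes, 0.028 for neurons, 0.00040 for cell cycle and -0.016 for phototransduction. When each array was left out, signs changed within these ranges: -0.0042 to 0.0042 for cuticle, -0.033 to 0.016 for ribosomal proteins, -0.044 to 0.045 for ecdysone response, -0.0085 to 0.030 for eye development, -0.025 to 0.055 for fat body, -0.026 to 0.088 for salivary gland, -0.0059 to 0.043 for the respiratory chain and -0.030 to 0.028 for neurons. B52 ranged over -0.13 to 0.019. Leaving out 1 array moved the mean of 9 of the 64 genes called over their list alone, and of 3 of the 20 leading genes, by over 1.5 times. Of the comparisons for named genes, 442 kept their side of the threshold and their sign, 136 gained a call (75 of them with the replicate block) and 9 lost one, those of pen-2, Gmap and GstD5 with 1 value per gene. These 3 lost theirs with scaling (adjusted p = 0.134), with at least 1 array per replicate (0.194) and without the array with dASF/SF2 in Cy5 of replicate 2 (0.228). Of those for gene lists, 179 kept both. Without signals over background, how far dim spots limit these values was not analysed here.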

Other observations

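The tests on sign patterns, unnamed positions with and without the lowest probes, other broadly used gene lists, intervals over position blocks, the 2 corrections together, the length trend of lists and the gene families were chosen only after results had been seen. Families defined by a shared symbol prefix, 26 of them with at least 15 genes, were tested with camera at its preset correlation, and 3 were called. Besides the eIF genes (35 genes, mean -0.16 ± 0.04 SD, n = 2), which overlap the list of translation factors, these were the Vps genes of vacuolar and endosomal sorting, with 18 of 24 negative, a mean of -0.12 ± 0.03 and an adjusted p of 0.0164 in limma's camera, and the ionotropic receptor (Ir) genes, with 28 of 35 positive, a mean of 0.063 ± 0.002 and an adjusted p of 0.0401. With an estimated correlation on the 4 arrays the adjusted p was 0.694 for eIF, 0.694 for Vps and 0.834 for Ir. The Ir genes had a larger mean with the arrays not turned, 0.096, than turned, whereas that of the Vps genes was 0.016. The odorant-binding protein (Obp) genes, with 31 of 42 positive and a mean of 0.045 ± 0.019, the dpr genes of cell-surface recognition, with 15 of 16 positive and a mean of 0.084 ± 0.005, and the Mediator (MED) genes, with 17 of 24 positive and a mean of 0.084 ± 0.066, had an adjusted p of 0.0596 each.

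A set of unnamed probes set the replicates apart. At 7 positions of the array layout, each present in 24 repeats, the 168 probes had a median of -1.03 on the array with dASF/SF2 in Cy5 of replicate 2 and -1.77 on that with dASF/SF2 in Cy3, before turning. On the arrays of replicate 1 their medians were -0.0090 and -0.22. Of these probes 167 lay below -0.5 on both arrays of replicate 2 and 1 on both arrays of replicate 1, while 2 probes with 1 gene symbol lay below -0.5 on both arrays of replicate 2. In replicate 2 their medians thus had the same sign in both dye orientations. Without them the dye-swapped arrays of replicate 2 correlated with a Pearson r of -0.468 in place of -0.054, and those of replicate 1 at 0.229 in place of 0.236.

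The first pattern weighed is the 3616 probes with 1 sign on all 4 turned arrays: of the 8 sign patterns that 4 arrays can have, the one that follows the dye orientation alone gave as many, and the highest of the others gave 2729, but 8 patterns are too few for a share under 0.05. Position as the whole source is argued against by the replicate correlation only at the scale of 48 blocks of consecutive probe numbers. It was 0.545 after the median of each block was taken off and 0.548 before. The 95% interval of the former was 0.521 to 0.567 over 2000 resamples of the blocks. Position effects within a block would stay in these values, so they are left open. A dye effect in values that already are sample ratios cannot be told apart from a difference between the IPs: the 737 probes at positions unnamed in every repeat had a median of -0.152 over the unturned arrays, between the bounds set for either reading, with 138 negative and 21 positive on all 4 arrays against 46 each by chance, and 64 negative and 30 positive once turned. The 168 probes above are among them; without these the median over the other 569 was -0.038, inside the bound for a dye effect, but they were picked by their values, so this decides nothing. A difference in the RNA bound by the 2 proteins stays open and untested, since hybridisations of a sample against itself were not analysed here.

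The second pattern is the positive correlation of the dye-swapped arrays of replicate 1, a Pearson r of 0.236 over all probes and 0.169 over named probes, where those of replicate 2 had -0.054 and -0.565. With position blocks taken off it was 0.162 (95% interval 0.135 to 0.189 over 2000 resamples of the 48 blocks) and among named probes alone 0.169 (0.124 to 0.208). Both intervals reach below the bound of 0.15 set for excluding position or unnamed probes as the whole source, so both stay open. With both corrections it was 0.071 (0.042 to 0.099), so the 2 may act together. Per the labels both arrays of a pair are dye swaps of each other, and no biological explanation was tested. If the values already are sample ratios, a part common to both arrays of a pair is the IP comparison, and this stays open.

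The third pattern is that longer genes lay lower. Across 9901 genes, which are not independent replicates, Spearman's rho between genomic length and turned value was -0.165 in replicate 1 and -0.171 in replicate 2, values that are the pattern itself and test no explanation. The 4 equal groups of genes by length had medians of 0.047, -0.00060, -0.041 and -0.021 from short to long, so the trend did not run through the longest genes. With the mean of the unturned arrays rho was 0.015, but since the direction of the values is not settled, either mean can hold the dye effect, and a length effect through the samples cannot be told apart from one through the dyes. After a smooth trend on length was taken off, the list means were -0.15 for translation factors, -0.13 for proteasome and 0.21 for glial markers, against -0.17, -0.13 and 0.17 before.

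One hypothesis concerned the proteasome, whose testis-biased and other copies carry a suffix in their symbols: genes used in all tissues may lie on the negative side while their copies do not. The 27 genes without a copy suffix had a median of -0.19, 24 of them negative, and the 9 copies a median of 0.015, 4 of them negative. The split was not clean, as genes named after their values were seen show. Prosbeta3 (-0.012), Prosbeta4 (0.0043), Prosbeta5 (0.0375) and Prosbeta6 (-0.0087), without a suffix, lay near 0, whereas Prosbeta2 (-0.277) and Prosbeta7 (-0.161) lay lower. The copies Prosbeta2R1 (-0.11) and Prosbeta5R2 (-0.129) were negative. The difference of -0.203 had a 2-sided permutation p of 0.00081 over 100000 resamples of the gene labels, in which genes are taken as independent. The medians were -0.19 and -0.0070 in replicate 1, and -0.19 and -0.0025 in replicate 2. Other broadly used genes differed among themselves. Translation factors had a median of -0.168 (95% bootstrap interval -0.216 to -0.118; 37 of 42 negative) and the CCT chaperonin genes, named after their values were seen, -0.170 (-0.214 to -0.109; 8 of 8 negative). Cytosolic ribosomal proteins had -0.003 (-0.049 to 0.022; 17 of 33 negative) and the mitochondrial respiratory chain 0.00050 (-0.026 to 0.020; 35 of 70 negative). These intervals come from 10000 resamples of a list's genes, taken as independent, and do not measure the spread between the 2 replicates. The list means of the respiratory chain were 0.048 in replicate 1 and -0.041 in replicate 2. Those of cytosolic ribosomal proteins were -0.0185 and -0.0219. With genes taken as independent, the values near 0 of these 2 lists argue against a shift of broadly used genes in general. What sets the proteasome genes apart from their copies stays open. Copies that are absent from larval tissue would have ratios near 0 under any reading of the values, and signal over background was not analysed here.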
